A study of Mus musculus with 15 samples.

How the data were processed

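RNA from sorted mouse pancreatic islet cells was profiled on 15 Affymetrix Mouse Gene 1.0 ST arrays, with 5 arrays titled as beta cells, 5 as alpha cells and 5 as Pdx1-deficient cells. Per the labels, 500 ng of total RNA entered each labelling reaction, the control cells carried a YFP reporter and came from mice 2 months old, and the Pdx1-deficient cells were taken 5 days after tamoxifen. Groups were taken from the sample titles. The genotype labels pair the beta samples with a glucagon-Cre driver and the alpha samples with an insulin-promoter CreER driver and a heterozygous floxed Pdx1 allele, the reverse of the cells in which these drivers are usually active. The signals of the identity lists ran with the titles. In arrays titled alpha, 5 of 17 beta-cell identity genes were lower and 0 higher, and 5 of 13 alpha-cell identity genes were higher and 0 lower. These list counts argue against exchanged titles of these 2 groups. Among genes chosen after their values were seen, Ins2 read 11.90 in beta and 12.00 in alpha arrays, against the titles. Mafa read 6.52 and 6.38, and Gcg 12.35 and 12.74. The sources used here do not say which exon was deleted, whether the controls received tamoxifen, or how the Pdx1-deficient cells were sorted. They also do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

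The deposited values are signals on what the range of 2.11 to 13.45 shows to be a log2 scale, 1 per transcript cluster and array. Per the submitters' processing notes the authors used Affymetrix Expression Console, with no version given. The summarization method, the background correction, the statement of the log base and the genome build are not given in the sources used here, and fold changes hold only if the base is 2. Array medians ran from 5.88 to 6.05, no value was missing, and the correlation between pairs of arrays over all clusters ran from 0.907 to 0.979. Pdx1-deficient replicates 4 and 5 had the highest medians (6.03 and 6.05) and the lowest mean correlations with their own group (0.937 and 0.940, where the other 3 had 0.953 to 0.956). The 25th and 75th percentiles of these 2 arrays, 4.80 and 7.24 in replicate 4 and 4.80 and 7.25 in replicate 5, lay closer together than those of beta arrays. In beta arrays they were 4.55 to 4.66 and 7.34 to 7.40. Alpha replicates 1, 3, 4 and 5 had 4.71 to 4.76 and 7.24 to 7.36, also closer together than in beta arrays. The array labelled alpha replicate 2 had 4.66 and 7.33. No 2 arrays held identical values. For arrays the number per group, 5, limits the precision.

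The value table held 35556 transcript clusters. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12146, and clusters with several or none were named as no gene. Gene IDs of 21698 single-symbol clusters were matched to the reference gene table (assembly GRCm38.p6, used for names only), and 0 symbols changed. Each of the 19938 genes was represented by its single-symbol cluster with the highest mean over the 15 arrays; 999 genes had more than 1 cluster. No coordinates are given, because the build behind the array annotation was not known.

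Differences between groups were tested on the deposited log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in a fit of 3 group means over all 15 arrays without a block, and p-values were adjusted by the method of Benjamini and Hochberg over the 19938 genes with a threshold of 0.05. All 3 pairwise comparisons were made. Pdx1 itself was also tested with a two-sided exact permutation test over the 252 splits of the 10 arrays compared. Alpha-enriched and beta-enriched genes were those at least 2-fold higher in one of the 2 control groups with an adjusted p under 0.05. A gene's share of the alpha-beta difference was its change from beta to Pdx1-deficient arrays divided by its change from beta to alpha arrays, and medians over genes are given without a p-value because the genes were picked on the same arrays.

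The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names Pdx1, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose 2 groups of arrays did not overlap (5 and 5 for Pdx1-deficient against alpha cells), and up to 4 members per gene list past the threshold, or up to 2 where none passed. Predicted genes with Gm or Rik symbols were skipped, and 1 gene that the rule names is not reported here. The 17 lists covered beta-cell identity, alpha-cell identity, delta, PP and epsilon cells, the shared endocrine program, progenitor and dedifferentiation genes, glucose sensing and exocytosis, genes disallowed in beta cells, the unfolded protein response, oxidative phosphorylation, cell cycle, interferon response, immediate early and dissociation stress, and markers of acinar, duct, endothelial, leukocyte and stromal or stellate cells. Between 8 and 21 members per list were measured by a single-symbol cluster under the listed name or a synonym, other members were not analysed here, and no gene stood in more than 1 list. Lists were tested with limma's camera, which compares a list's genes with all others, at a preset correlation between genes of 0.01, with adjustment over the 17 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it.

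Both main comparisons use the same 5 beta arrays, and chance deviations of these arrays enter both. The agreement between them was therefore set beside 100 simulated pairs of unchanged groups compared with the same beta arrays (for shares, signs and correlation), the overlap of independent lists of the same sizes, and all 20 assignments of the beta arrays to separate sets of 2 and 3, with the enriched genes for the shares taken as the 65 and 201 genes farthest apart between alpha arrays and the beta arrays set aside for them. The fit and the list test were tested on simulated data before use, with 200 genes changed in each simulated comparison of 19938 genes. For Pdx1-deficient against beta cells 34.3%, 80.6% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 8 false calls among 153. For alpha against beta cells the shares were 43.3%, 77.6% and 98.5%, with 4 false calls among 150. The 1 list moved in the simulation, by 0.4, was called and 0 others were. Simulated genes varied independently of each other, so this says nothing about lists of correlated genes. In the data the estimated correlation ran from -0.0275 for glucose sensing and exocytosis to 0.786 for acinar genes.

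Alternatives changed 1 choice at a time: the mean of a gene's clusters, a filter on dim clusters, a second quantile normalization, subtraction of array medians, trend and robust moderation, array weights, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each of the 15 arrays in turn. For the shares, the linear scale and a 4-fold definition of enriched genes were also tried. Leaving out the array labelled Pdx1-deficient replicate 1 together with the array labelled alpha replicate 2, and leaving out alpha replicate 5 as well, were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.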

Results

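Gene expression was measured in 15 samples of mouse islet cells: 5 of beta cells, the insulin-producing cells, 5 of alpha cells, the glucagon-producing cells, and 5 labelled as deficient in the transcription factor Pdx1, taken 5 days after tamoxifen. Control alpha and beta cells had been sorted by a YFP reporter. Values are log2 signals for 19938 genes per array, with array medians between 5.88 and 6.05. The series title sets the question: whether Pdx1 keeps an alpha-cell program repressed and beta-cell identity in place.

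Pdx1, measured by transcript cluster 10527565, had a log2 signal of 9.14 ± 0.20 (SD, n = 5) in beta cells and 7.86 ± 0.39 (SD, n = 5) in alpha cells. In the arrays labelled Pdx1-deficient it was 7.75 ± 0.92 (SD, n = 5). Replicates 2 to 5 of that group read 7.83, 7.68, 6.53 and 7.59, below every beta array. The array labelled Pdx1-deficient replicate 1 read 9.12, inside the beta range of 8.85 to 9.33, so the target gene went against its label. Pdx1 differed from beta cells by -1.39 (SE 0.34) in the group as labelled, which did not pass across all genes (limma adjusted p = 0.0575; exact permutation p = 0.0238). Without the array labelled Pdx1-deficient replicate 1 the difference was -1.74 (limma adjusted p = 0.00617, with 0.00617 to 0.133 over all alternatives). Pdx1 fell by 1.28 in alpha compared with beta cells (SE 0.34, limma adjusted p = 0.0473), with an exact permutation p of 0.00794, the smallest that 5 against 5 arrays allow; the limma adjusted p ran from 0.00719 to 0.107 over the alternatives. Pdx1-deficient and alpha arrays differed by -0.11 (limma adjusted p = 0.994, exact permutation p = 0.81). Whether this cluster's probes lie in the deleted part of the gene was not known. Directions given for Pdx1-deficient and alpha cells include the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2 unless stated.

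**Figure D1:**
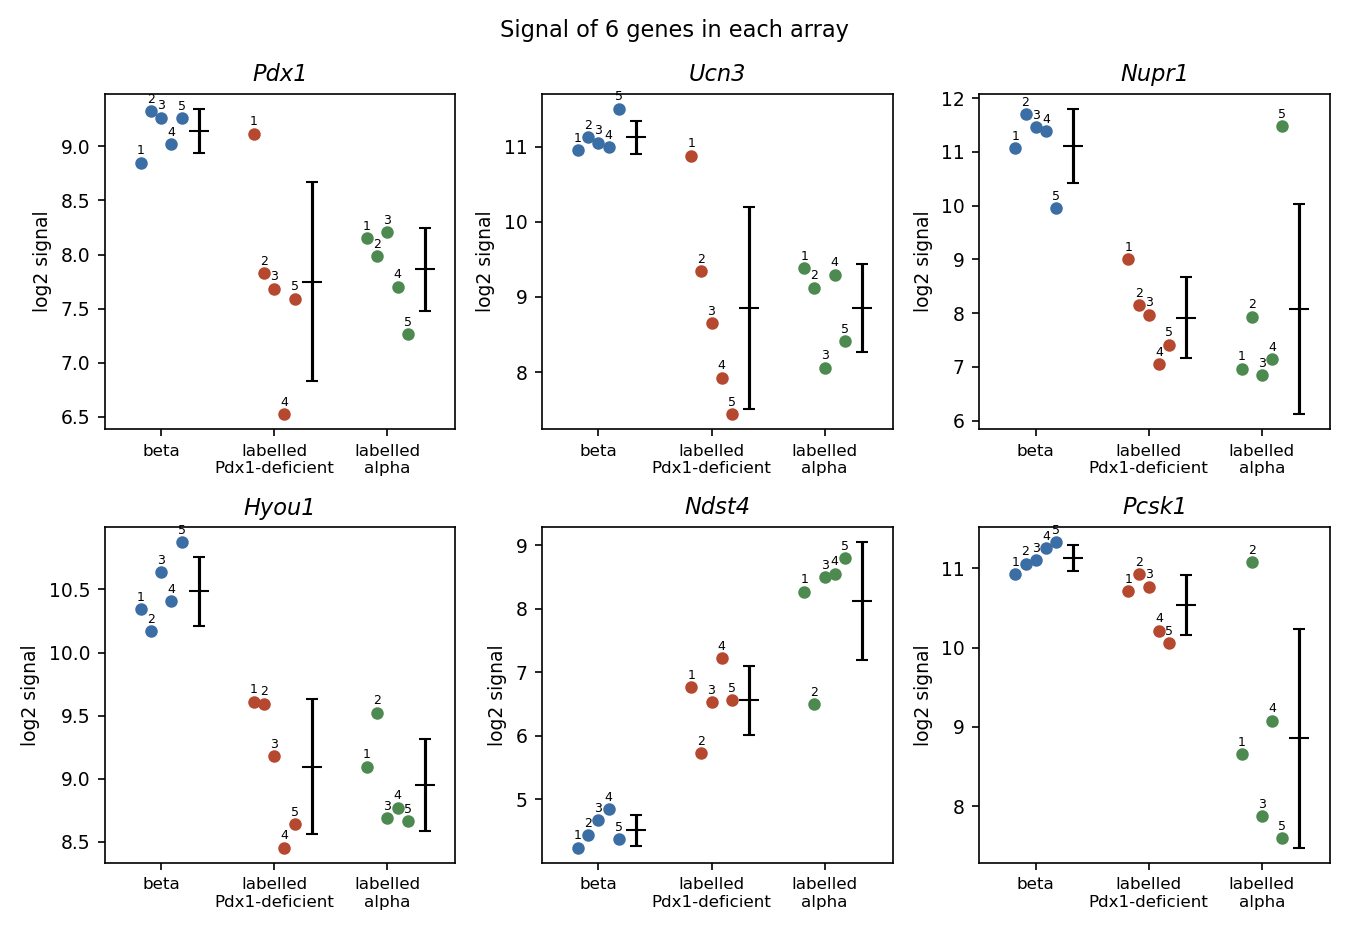
Log2 signal (vertical axes) of Pdx1, Ucn3, Nupr1, Hyou1, Ndst4 and Pcsk1 in each of the 15 arrays, with replicate numbers beside the points and bars for the mean ± SD of each group of 5 arrays as labelled. Pdx1 in the array labelled Pdx1-deficient replicate 1 (9.12) lay among the beta arrays (8.85 to 9.33), and Ndst4 in the array labelled alpha replicate 2 (6.50) lay below the other alpha arrays (8.27 to 8.79).

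The first comparison asked which genes differed between the 5 arrays labelled Pdx1-deficient, replicate 1 with its beta-level Pdx1 included, and beta cells. Ucn3, which encodes the peptide hormone urocortin 3 of mature mouse beta cells, fell 4.85-fold, from 11.13 ± 0.22 (SD, n = 5) in beta cells to 8.85 ± 1.35 (SD, n = 5) in the arrays labelled Pdx1-deficient, a log2 difference of -2.28 (SE 0.49, limma adjusted p = 0.0389). Nupr1, a stress-induced nuclear protein gene, fell 9.15-fold from 11.11 ± 0.69 to 7.92 ± 0.75 (limma adjusted p = 0.0491). It passed the threshold in only 3 of 15 leave-outs, with a highest limma adjusted p of 0.121. Ndst4, a heparan sulfate sulfotransferase gene on the alpha-cell list, rose 4.14-fold from 4.51 ± 0.24 to 6.56 ± 0.54 (limma adjusted p = 0.0316). Its mean beta signal lay below the 25th percentile of each beta array (4.55 to 4.66). It may hold background, so the fold is better read as a lower bound. Of 19 genes of the unfolded protein response, which serve protein folding in the endoplasmic reticulum, 8 fell and 0 rose.

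In all, 217 of 19938 genes passed the threshold, 32 higher and 185 lower in the arrays labelled Pdx1-deficient, and 8 and 57 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 4344 genes. The 5 arrays of each group did not overlap for 1188 genes, 5.96% where chance gives 0.794%. Besides Ndst4, the named rises were Dbpht2 (1.73 on the log2 scale), the receptor phosphatase gene Ptprd (1.67), the receptor tyrosine kinase gene Kit (1.56), the imprinted zinc-finger gene Zim1 (1.52), the glutamate receptor gene Gria3 (1.48), Syt16 (0.94), Tra2a (0.77), Basp1 (0.75) and Rbms3 (0.71). Their adjusted p-values lay between 0.0164 for Ptprd and 0.0381 for Zim1. Named falls after Nupr1 and Ucn3 were Tcim (-3.00), Nell1 (-1.92), the epithelial sodium channel subunit gene Scnn1b (-1.76), the coatomer gene Copz2 (-1.63), Clptm1l (-1.59), the potassium channel partner gene Kcnip1 (-1.55), Mydgf (-1.53) and the copper transporter gene Slc31a1 (-1.48). Their adjusted p-values lay between 0.0234 for Scnn1b and 0.0429 for Kcnip1.

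How many genes passed the threshold rested on single arrays: 548 genes passed without the array labelled Pdx1-deficient replicate 1, but 21 without replicate 2, 1 without replicate 4 and 0 without replicate 5 of that group (limma; 3094 genes at an unadjusted p under 0.05), and 4, 69, 3 and 4 without beta replicates 1, 3, 4 and 5. The 217 genes kept their sign and an unadjusted p under 0.05 in each of the 15 leave-outs. Median ratios to their log2 differences were 0.933 without Pdx1-deficient replicate 4 and 0.942 without replicate 5. The genes were picked on arrays that each leave-out largely keeps, so this was close to given and is no separate support. None of the 26 named genes past the threshold stayed past it in all 15 leave-outs, where their highest adjusted p ranged from 0.0629 to 0.121, while all 26 kept their direction in every alternative and passed without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2. Number and direction of calls moved with the scaling: with array medians subtracted 615 genes passed, 26 higher and 589 lower (4.23% higher against 14.7%), and quantile normalized again 29, 5 higher and 24 lower (17.2% higher). In other fits 401 passed with dim clusters removed, 121 with trend and robust moderation and 89 with only the 2 groups.

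Of the 19 measured unfolded protein response genes, 8 fell, 0 rose and 11 did not pass; 17 fell when adjusted over the list alone, and 13 across all genes without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2. Creld2 fell by 1.40 on the log2 scale, the endoplasmic reticulum chaperone gene Hyou1 by 1.39 (from 10.49 ± 0.27 to 9.10 ± 0.53, SD, n = 5), Sdf2l1 by 1.30 and the disulfide isomerase gene Pdia6 by 1.17. The list's median was -0.68 and camera gave an adjusted p of 9.19e-16, with adjusted p = 0.0548 with an estimated correlation and 0.000729 by fry. Its mean was 9.52 in the array labelled Pdx1-deficient replicate 1 and 9.27, 9.28, 8.94 and 8.88 in replicates 2 to 5. Beta arrays had 9.73 to 10.07. The 20 measured oxidative phosphorylation genes, which encode parts of the mitochondrial respiratory chain, had a median of -0.41 and were lower as a list by camera (adjusted p = 2.18e-09), although 0 passed singly and 6 fell when adjusted over the list alone. The list mean was 9.46, 9.40 and 9.38 in the array labelled Pdx1-deficient replicate 1 and in replicates 2 and 3, 8.94 and 9.02 in replicates 4 and 5, and 9.47 to 9.93 in beta arrays. The largest differences were -1.06 in Ndufv1 (limma adjusted p = 0.114) and -0.86 in Ndufb8 (limma adjusted p = 0.173). This call was lost with adjusted p = 0.313 with an estimated correlation, and fry gave 0.038.

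Of the 17 measured beta-cell identity genes, 1 fell, Ucn3, and 7 fell when adjusted over the list alone; without the array labelled Pdx1-deficient replicate 1, 7 fell across all genes. The list was lower by camera (median -0.39, adjusted p = 0.00267, 9.82e-07 to 0.123 over the alternatives), with adjusted p = 0.621 with an estimated correlation and 0.155 by fry. Its mean in the array labelled Pdx1-deficient replicate 1 was 9.57, above the beta arrays (9.24 to 9.44). Of the 13 measured alpha-cell identity genes 1 rose, Ndst4, also when adjusted over the list alone, and the list had a median of 0.24 and a camera adjusted p of 0.0502, which did not pass (adjusted p = 0.768 with an estimated correlation). It passed without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2 (adjusted p = 0.0399, 0.000487 to 0.147 over the alternatives).

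Among the remaining lists 2 single genes passed. The synaptic vesicle gene Syp of the shared endocrine program fell by 0.65 (limma adjusted p = 0.0464; 1 of 17 when adjusted over the list alone; list adjusted p = 0.449). Bhlha15, a transcription factor gene of secretory cells on the acinar list, fell by 1.09 (limma adjusted p = 0.0316; 1 of 21 when adjusted over the list alone; list adjusted p = 0.597). Stromal and stellate genes (median 0.18, camera adjusted p = 0.0502; Rgs5 0.48, Sparc 0.36) and immediate early and dissociation stress genes (median 0.23, camera adjusted p = 0.0512; Nr4a1 1.26, Atf3 1.10) lay near the threshold, with adjusted p = 0.768 with an estimated correlation for both. By adjustment within the list, 0 stromal genes and 2 stress genes rose. The camera adjusted p was 0.255 for delta, PP and epsilon cells (Hhex -0.59, Casr -0.54), 0.875 for progenitor and dedifferentiation (Aldh1a3 -0.55, Neurog3 -0.52), 0.597 for glucose sensing and exocytosis (Rab3a -0.80, Pcx -0.60) and 0.243 for genes disallowed in beta cells (Ldha 0.49, Pdgfra 0.24). It was 0.961 for cell cycle (Mki67 0.58, Ccnd1 -0.48), 0.983 for interferon response (Usp18 -0.83, Irf1 0.49), 0.558 for duct (Cldn7 -0.46, Muc1 0.32), 0.358 for endothelial (Emcn 0.23, Tie1 0.16) and 0.255 for leukocyte genes (C1qa -0.71, C1qb 0.33). Adjusted over the list alone, 1 delta, PP and epsilon gene, 3 glucose sensing genes and 1 interferon gene fell, 1 glucose sensing gene and 1 disallowed gene rose, and 0 genes of the progenitor, cell cycle, duct, endothelial and leukocyte lists passed. Signs differed between median, mean and test for glucose sensing and acinar genes (median positive, mean and camera negative), cell cycle genes (median and mean positive, camera negative) and progenitor genes (fry positive, the others negative).

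**Figure D2:**
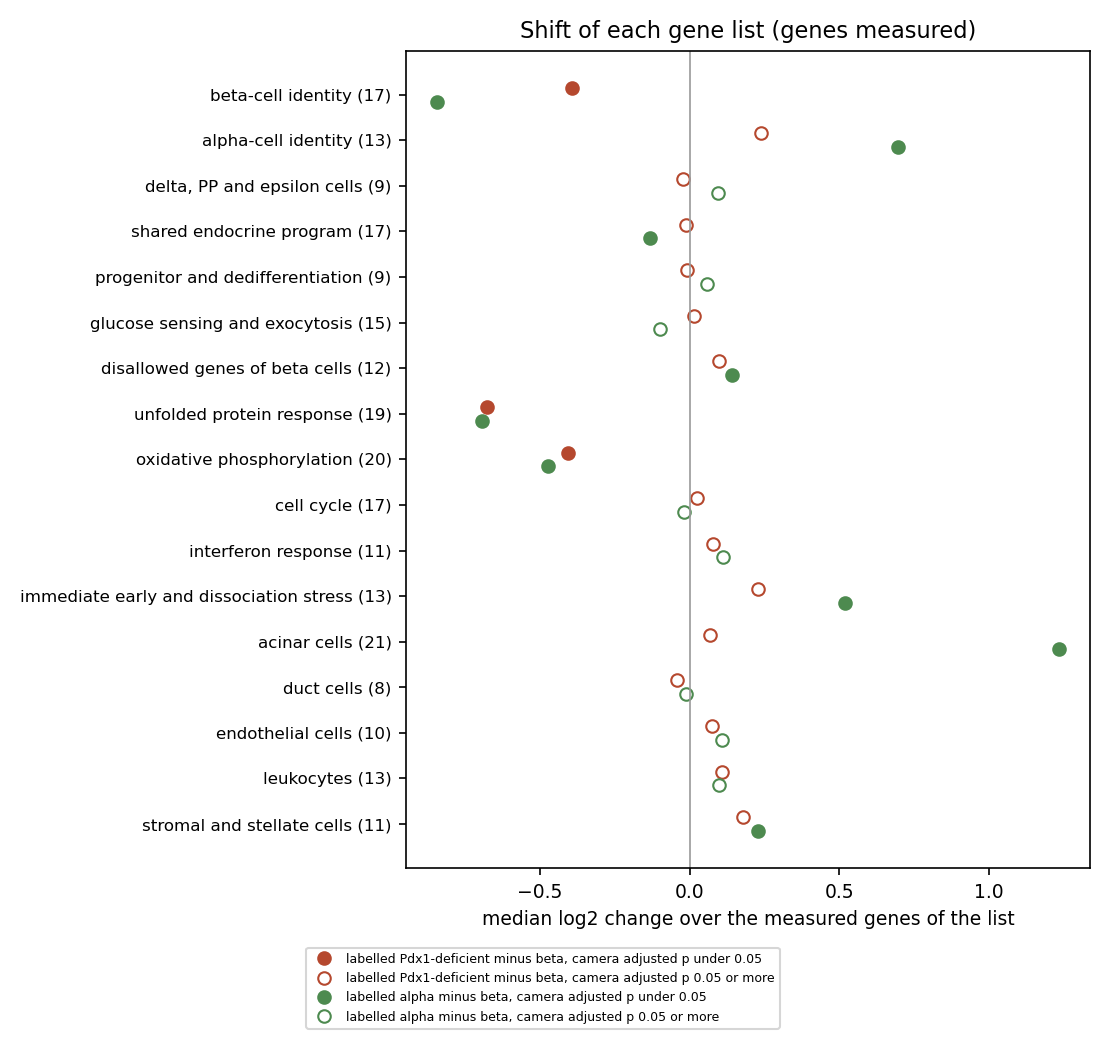
Median log2 change over the measured genes of each of the 17 lists (horizontal axis; number of measured genes in brackets) in the arrays labelled Pdx1-deficient and in the arrays labelled alpha, each minus beta. Filled points passed camera at an adjusted p under 0.05; unfolded protein response genes lay at -0.68 and -0.69 and alpha-cell identity genes at 0.24 and 0.70.

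The comparison of control alpha with beta cells gave the reference for cell identity. Ndst4 rose 12.2-fold in alpha cells, from 4.51 ± 0.24 to 8.12 ± 0.92 (SD, n = 5, log2 difference 3.61, SE 0.36, limma adjusted p = 0.00056). With its dim beta signal this fold, too, is better read as a lower bound. The gene of the pyruvate dehydrogenase kinase Pdk4 rose 12.1-fold, from 5.92 ± 0.85 to 9.52 ± 1.13. Slc2a2, which encodes the glucose transporter of mouse beta cells, fell 4.17-fold from 9.85 ± 0.34 to 7.79 ± 0.67 (limma adjusted p = 0.0442), and Ucn3 fell 4.83-fold from 11.13 ± 0.22 to 8.85 ± 0.59. The array labelled alpha replicate 2 lay apart from the other 4: its Ndst4 signal was 6.50 where they read 8.27 to 8.79.

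Between alpha and beta cells 806 of 19938 genes passed, 178 higher and 628 lower in alpha cells, of which 65 and 201 by at least 2-fold; 4137 genes had an unadjusted p under 0.05. The arrays of the groups did not overlap for 1264 genes (6.34%, where chance gives 0.794%). Further named rises were Peg10 (2.92 on the log2 scale), Mctp2 (2.81), the glycosyltransferase gene Galnt13 (2.75), the kinase gene Wnk3 (2.36), Ptprd (2.32), the chromatin remodeller gene Smarca1 (2.02) and Rab3c (2.01). Named falls were the calcium-binding protein gene S100a4 (-2.90), the protease gene Bace2 (-2.42), the ETS factor gene Etv5 (-2.38), Kcnip1 (-2.31), the cyclic GMP phosphodiesterase gene Pde5a (-2.26), Tmem255a (-2.16), the villin gene Vil1 (-2.13) and Cib3 (-2.11). Of the 43 named genes past the threshold, 26 stayed past it in all 15 leave-outs, and all 43 kept their direction. The count was 1430 without the array labelled alpha replicate 2, and 427, 328, 439 and 415 without alpha replicates 1, 3, 4 and 5. It was 372, 527, 393 and 393 without beta replicates 1, 3, 4 and 5, and with array medians subtracted 1182 genes passed, 123 higher and 1059 lower (10.4% higher against 22.1%).

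Of the 13 measured alpha-cell identity genes 5 rose in alpha cells and 0 fell: Ndst4, Smarca1, the ETS factor gene Etv1 (1.66), the amino acid transporter gene Slc7a2 (1.32) and, chosen after its values were seen, the homeobox gene Irx2 (0.63). Adjusted over the list alone, 11 rose, and camera gave an adjusted p of 5.27e-10 (adjusted p = 0.0477 with an estimated correlation, fry 0.000303). Without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2, 9 rose across all genes. Of the 17 measured beta-cell identity genes 5 fell: the prohormone convertase gene Pcsk1 (-2.27), Ucn3, Slc2a2, the glucose-6-phosphatase gene G6pc2 (-1.65) and, chosen after its values were seen, the homeobox gene Nkx6-1 (-1.07). Adjusted over the list alone, 10 fell, and camera gave an adjusted p of 6.6e-06, lost with adjusted p = 0.16 with an estimated correlation, while fry gave 0.0116. Without the same pair of arrays, 8 fell across all genes.

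Of the 19 unfolded protein response genes 11 fell in alpha cells (16 when adjusted over the list alone), among them Creld2 and Hyou1 (both -1.54), Sel1l (-1.37) and Sdf2l1 (-1.34); the list's adjusted p was 2.03e-14, and adjusted p = 0.0477 with an estimated correlation. Of 20 oxidative phosphorylation genes 2 fell, Cycs (-0.77) and Sdha (-0.75), and 10 when adjusted over the list alone, with 6 across all genes without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2 (camera adjusted p = 1.82e-09, but adjusted p = 0.16 with an estimated correlation). Immediate early and dissociation stress genes were higher in alpha cells (median 0.52, adjusted p = 6.6e-06, but adjusted p = 0.286 with an estimated correlation): 2 of 13 rose, the transcription factor gene Atf3 (2.30) and Zfp36 (0.72), and 8 when adjusted over the list alone. Without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2, 7 of these 13 rose. By fry the adjusted p was 0.000303 for the unfolded protein response, 0.0116 for oxidative phosphorylation and 0.024 for immediate early and dissociation stress genes.

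Acinar genes, which encode digestive enzymes of the exocrine pancreas, were higher in alpha cells by camera (median 1.23, adjusted p = 0.0122, 0.000103 to 0.488 over the alternatives, but adjusted p = 0.576 with an estimated correlation). This rested on alpha replicate 5, whose list mean was 10.77 against 5.74 to 6.80 in the other alpha arrays, and the call was lost without it; of the 21 genes 0 rose, and Bhlha15 alone fell, by 1.16, across all genes and when adjusted over the list alone. Stromal and stellate genes were higher (median 0.23, adjusted p = 0.00206, but adjusted p = 0.331 with an estimated correlation), with 1 rise, the pericyte gene Rgs5 (1.07), and 3 when adjusted over the list alone. Genes disallowed in beta cells were higher (median 0.14, adjusted p = 0.0122, 0.00226 to 0.0609 over the alternatives, but adjusted p = 0.358 with an estimated correlation) with 0 passing singly and 1 when adjusted over the list alone; Oat differed by 1.40 (limma adjusted p = 0.0523) and Mgst1 by 0.35. This call was lost without alpha replicate 1. In the shared endocrine program 3 of 17 genes fell, Syp (-0.84), the granule protein gene Chga (-0.49) and Scg3 (-0.34), and 5 when adjusted over the list alone (camera adjusted p = 0.0341, 0.00319 to 0.65 over the alternatives, but adjusted p = 0.446 with an estimated correlation). Its call was lost without alpha replicate 1, alpha replicate 5 or beta replicate 3. Fry gave an adjusted p of 0.306 for acinar, 0.0325 for stromal and stellate, 0.042 for disallowed and 0.102 for shared endocrine genes.

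The other lists did not pass camera in alpha against beta cells. For delta, PP and epsilon cells (adjusted p = 0.305) the retinol-binding protein gene Rbp4 rose by 1.04 and the calcium-sensing receptor gene Casr fell by 0.60, across all genes and when adjusted over the list alone. For glucose sensing and exocytosis (camera adjusted p = 0.191, but 0.0325 by fry) the pyruvate carboxylase gene Pcx fell by 0.91 and Rab3a by 0.79, by both adjustments. For duct cells (adjusted p = 0.305) the claudin gene Cldn7 fell by 0.75, and 2 genes fell when adjusted over the list alone. Adjusted p was 0.772 for progenitor (Aldh1a3 -0.71, Neurog3 -0.48), 0.764 for cell cycle (Ccnd1 -0.61, Mcm6 -0.28), 0.581 for interferon (Cxcl10 0.74, Usp18 -0.69), 0.175 for endothelial (Emcn 0.30, Kdr 0.18) and 0.0591 for leukocyte genes (Tyrobp 0.41, Lyz2 0.38). Adjusted over the list alone, 1 progenitor gene fell, 2 interferon genes rose and 1 fell, and 0 genes of the other 3 lists passed. Without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2, 5 shared endocrine genes and 2 duct genes fell and 2 stromal genes rose across all genes. The progenitor list had a positive median and a negative mean.

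Identity genes were then followed from beta to Pdx1-deficient cells. Of the 201 beta-enriched genes, 51 fell in the arrays labelled Pdx1-deficient, 0 rose, and all 201 had a negative difference. Of the 65 alpha-enriched genes, 9 rose, Ndst4 and Ptprd among them, 0 fell, and 61 had a positive difference. Both sets were picked with the same beta arrays: with separate ones 88.6% to 98.5% of beta-enriched genes had a negative and 64.6% to 90.8% of alpha-enriched genes a positive difference. Of the 32 genes that rose in the arrays labelled Pdx1-deficient 18 also rose in alpha cells. Of the 185 that fell 128 also fell in alpha cells, with 0 opposite changes. These counts share the beta arrays too, and no value for unchanged groups was computed for them. Without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2, with enriched genes defined anew, 155 of 366 beta-enriched genes fell and 13 of 102 alpha-enriched genes rose. Scaling moved these counts as well. Quantile normalized again, 12 of 147 fell and 4 of 58 rose, and with array medians subtracted 121 of 296 fell and 10 of 52 rose.

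Overlaps of 51 and 9 genes compare with 1.87 and 0.104 for independent lists, which do not share beta arrays. These counts too rested on single arrays, with enriched genes defined anew in each fit, falling to 0 and 0 without replicate 5, to 0 and 1 without replicate 4 and to 10 and 3 without replicate 2 of the Pdx1-deficient group. Calls and not differences were lost there: the beta-enriched share defined below was 0.638 without replicate 5 and 0.651 without replicate 4, against 0.690. They were 2 and 2, 1 and 2, and 1 and 2 without beta replicates 1, 4 and 5, 24 beta-enriched genes without beta replicate 3, 79 and 15 without the array labelled alpha replicate 2, and 114 beta-enriched genes without the array labelled Pdx1-deficient replicate 1. With separate beta arrays the 20 splits called a median of only 8 beta-enriched and 3 alpha-enriched genes, so that their median overlaps of 0 and 0 say little. Over all genes the log2 changes of the 2 comparisons correlated at 0.770 (across genes, which are not independent replicates), where the simulation gave 0.518 on average (-0.00733 to 0.866) and the splits 0.381 to 0.636. The covariance was 0.0838 against 0.0209 in the simulation, a difference of 0.0628, and 0.0551 to 0.0758 in the splits. Signs were the same for 83.2% of genes, against 68.6% (51.3% to 84.3%) in the simulation.

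Per gene, the median share of the alpha-beta difference reached in the arrays labelled Pdx1-deficient was 0.690 for beta-enriched and 0.325 for alpha-enriched genes. Simulated unchanged groups gave 0.529 (-0.0993 to 1.13) and 0.476 (-0.228 to 1.16) with shared simulated beta arrays. In them the alpha arrays did not differ from the beta arrays either, so these shares divide noise by noise. They cannot say what share unchanged Pdx1-deficient cells would give for genes that do differ between alpha and beta cells. With separate beta arrays, and as many genes picked anew in each split from its own arrays, the shares were 0.467 to 0.638 and 0.0743 to 0.300. By array, the beta-enriched share was 0.417 in the array labelled Pdx1-deficient replicate 1 and 0.668, 0.571, 0.876 and 0.920 in replicates 2 to 5, a mean of 0.690 ± 0.210 (SD, n = 5). The alpha-enriched share was 0.491 in the array labelled replicate 1 and 0.315, 0.346, 0.264 and 0.298 in the others, a mean of 0.343 ± 0.088 (SD, n = 5). The alpha-enriched median was 0.182 without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2, 0.5035 without beta replicate 3 and slightly lower than that without alpha replicate 5.

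**Figure D3:**
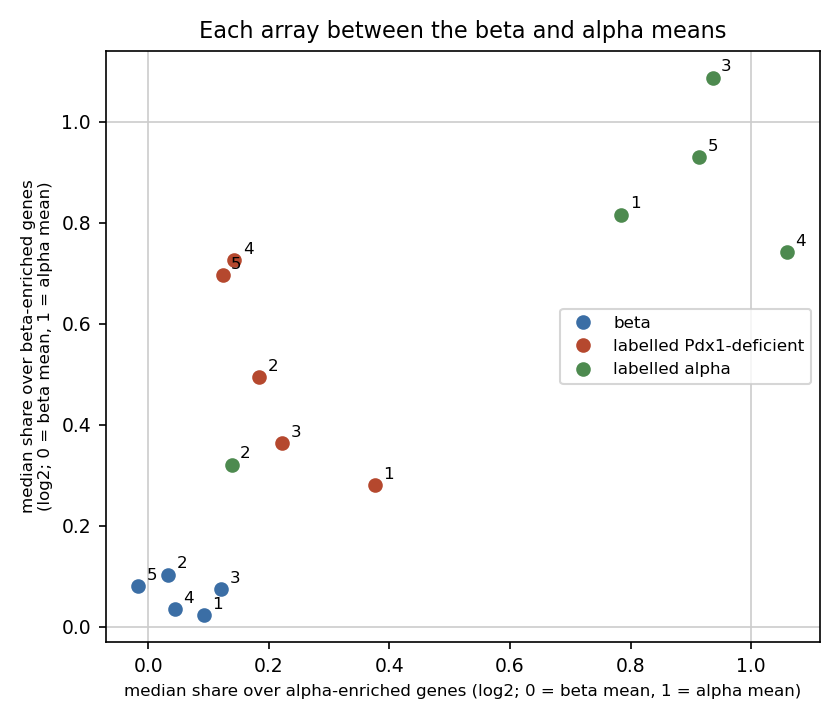
Position of each of the 15 arrays, with replicate numbers, as its median log2 share of the alpha-beta difference over 100 alpha-enriched (horizontal axis) and 100 beta-enriched genes (vertical axis), with 0 at the beta and 1 at the alpha mean and genes picked without that array and without the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2. The array labelled alpha replicate 2 lay at 0.139 and 0.321, away from the other alpha arrays (0.785 to 1.06 and 0.741 to 1.09), and Pdx1-deficient replicates 2 to 5 lay at 0.124 to 0.222 and 0.363 to 0.726.

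The last comparison set Pdx1-deficient against alpha cells. With the arrays as labelled, 0 of 19938 genes passed in limma (1197 at an unadjusted p under 0.05), 0 with the values quantile normalized again, and 1 each with trend and robust moderation and with array weights. Groups did not overlap for 127 genes, 0.637% where chance gives 0.794%. The largest differences of identity genes were 1.68 in Pcsk1 (10.53 ± 0.38 against 8.86 ± 1.37 in alpha cells, SD, n = 5, limma adjusted p = 0.394), -1.57 in Etv1 (limma adjusted p = 0.264) and -1.56 in Ndst4 (limma adjusted p = 0.319). Without the array labelled alpha replicate 2, 145 genes passed, 72 higher and 73 lower in Pdx1-deficient cells, and without the array labelled Pdx1-deficient replicate 1 as well 177 passed, 89 and 88. In the latter fit, chosen after seeing the data, Pcsk1 (2.19), Chga (0.60), Etv1 (-1.96), Ndst4 (-2.02), Rbp4 (-1.39), Oat (-2.18), Atf3 (-1.80) and Ier2 (-0.98) passed, with adjusted p from 0.000189 for Oat (highest over all alternatives 0.758) to 0.0302 for Ier2 (highest 0.899).

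Alpha-cell identity genes were lower as a list in Pdx1-deficient than in alpha cells (median -0.40, camera adjusted p = 8.18e-13, adjusted p = 0.0372 with an estimated correlation, fry 0.0239), with 0 of 13 passing singly and 7 lower when adjusted over the list alone. Other lists lower by camera were delta, PP and epsilon cells (Rbp4 -1.01, Hhex -0.98; adjusted p = 0.000387, but adjusted p = 0.17 with an estimated correlation), immediate early and dissociation stress (Atf3 -1.19, Ier2 -0.74; adjusted p = 0.000253) and acinar genes (Cpb1 -1.77, Zg16 -1.70; adjusted p = 9.96e-07), the last 2 with adjusted p = 0.697 with an estimated correlation. The acinar call was lost without alpha replicate 5. By the same adjustment, 2 delta, PP and epsilon genes, 0 stress genes and 0 acinar genes were lower. The 17 beta-cell identity genes had a median of 0.07 (adjusted p = 0.0807), with 1 higher when adjusted over the list alone, and unfolded protein response genes a median of 0.02 (adjusted p = 0.952; Ddit3 -0.71, Wfs1 0.49). Within their own lists 2 shared endocrine genes and 1 glucose sensing gene were higher and 1 disallowed gene lower. For the other 11 lists the adjusted p lay between 0.0807 and 0.952. Signs differed between median, mean and test for the unfolded protein response (camera negative, the others positive), oxidative phosphorylation (median negative, mean and camera positive) and leukocyte genes (median positive, the others negative).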

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

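Tests of the 2 single arrays below, and the test of beta-enriched genes alone with separate beta arrays, were chosen only after the result was seen. In 30 of 363 groups of 5 arrays, 1 array lay so far from the other 4 that its gap to the nearest exceeded 0.71 of the group's range; chance does this in about 1 in 20 groups, or 18.2 of these. The array labelled alpha replicate 2 stood apart in 10 of them, alpha replicate 5 in 7 and the array labelled Pdx1-deficient replicate 1 in 4.

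The array labelled Pdx1-deficient replicate 1 kept Pdx1 at 9.12, where replicates 2 to 5 of its group had 6.53 to 7.83, and its Slc2a2 signal was 10.46 against 6.71 to 7.94. Against an exchange with an alpha array stands its position over alpha-enriched genes, 0.3765 of the way from beta to alpha cells, where alpha replicates 1, 3, 4 and 5 lay at 0.785 to 1.06. Against a wrongly labelled beta sample stands the same position, 0.2552 above the highest beta array. A mixture of beta and alpha cells without Pdx1 loss cannot be told apart from other causes. The array's linear share over alpha-enriched minus that over beta-enriched genes was -0.236, below the lowest beta array (-0.207). Its distance of -0.1079 from the mean of the beta arrays was still smaller than the width of their range, 0.168. Incomplete deletion of Pdx1 in this sample, which the design allows, may also underlie its kept Pdx1 signal and was not tested. Alone it would place the array between the beta arrays and replicates 2 to 5. Over beta-enriched genes the array did lie there, at 0.280, where beta arrays had 0.022 to 0.103 and those replicates 0.363 to 0.726. Its position over alpha-enriched genes, 0.3765, lay above the 0.124 to 0.222 of those replicates. With 1 array, whether incomplete deletion was the only cause stays open.

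The array labelled alpha replicate 2 lay apart from the other 4 alpha arrays, at 0.139 and 0.321 of the way from beta to alpha cells over alpha-enriched and beta-enriched genes. Against beta cells mixed into this sort stands the gap of 0.4679 between its beta shares over genes that did and did not fall in Pdx1-deficient replicates 2 to 5, where the other alpha arrays had -0.0776 to 0.0689. Against a wrongly labelled beta sample stands its position over beta-enriched genes, 0.2176 above the highest beta array. A Pdx1-deficient sample under an alpha label may explain it: on an axis from alpha (0) to Pdx1-deficient cells (1) it lay at 0.9601, within the 0.838 to 0.962 of Pdx1-deficient replicates 2 to 5, although beta arrays lay at 0.913 to 0.978 on this axis too. No biological explanation was tested.

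Lower beta-enriched and higher alpha-enriched genes in the arrays labelled Pdx1-deficient could come from chance deviations of the beta arrays that both comparisons share. With separate beta arrays and genes picked without those set against the Pdx1-deficient arrays, the beta-enriched share was at least 0.4668 in all 20 splits, which speaks against this for the beta-enriched part. For the alpha-enriched part it cannot be told apart from a rise, since the share fell to 0.07429 in 1 split and had a median of 0.183. Against alpha cells mixed into the Pdx1-deficient sort as the source of the lower beta-enriched genes stands a gap between the linear shares. The beta-enriched share exceeded the alpha-enriched share by at least 0.4716 in each of Pdx1-deficient replicates 2 to 5. In beta arrays the alpha-enriched minus the beta-enriched share was -0.2075 to -0.0391. For the higher alpha-enriched genes such mixing cannot be told apart: their linear shares were 0.046 to 0.103 in these replicates and -0.007 to 0.053 in beta arrays. A loss of beta-cell expression after Pdx1 deletion remains a hypothesis, found and tested on the same arrays.

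Other splits of the 10 arrays were counted beside each number of genes, with 100 of the 126 splits drawn. For Pdx1-deficient against beta cells 1 of the 100, the real one, gave as many as 217 genes (highest other 3). For alpha against beta cells 1 of 100 gave 806 (highest other 122). The real grouping gave the most genes in both, but 1 of 100 is the smallest share these splits allow. Mixed splits also take a real group difference into the spread, which lowers their counts. Chance is thus unlikely for both but not excluded. For Pdx1-deficient against alpha cells the real count was 0 in limma (1197 at an unadjusted p under 0.05; 1 each with trend and robust moderation and with array weights), so that 100 of 100 splits gave as many by construction and the count says nothing about chance. Splits that exchanged the array labelled alpha replicate 2 for 1 array labelled Pdx1-deficient gave 123 genes for replicate 1, 32 for replicate 4, 16 for replicate 5 and 0 for replicates 2 and 3, which points to a structure of the samples around the array labelled alpha replicate 2.

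Genes in which the array labelled alpha replicate 2 stood apart are given with the gap as a share of the range, its value and the range of the other 4 arrays. Below them it had Ndst4 (0.772; 6.50 against 8.27 to 8.79), Pdk4 (0.776; 7.53 against 9.69 to 10.31), Mctp2 (0.761; 4.69 against 7.07 to 7.82), Wnk3 (0.782, 8.68 against 10.35 to 10.82), Atf3 (0.732, 8.15 against 10.36 to 11.17) and Etv1 (0.748, 9.21 against 10.45 to 10.86). Above them it had Clptm1l (0.739, 7.88 against 7.26 to 7.43), Chga (0.829, 12.58 against 11.96 to 12.06), Sdha (0.756, 9.70 against 9.07 to 9.22) and the mean of the oxidative phosphorylation genes (0.771, 9.48 against 9.10 to 9.18). Alpha replicate 5 was higher in Nupr1 (0.765, 11.48 against 6.85 to 7.94), Muc1 (0.745, 7.13 against 5.02 to 5.56), Kdr (0.891, 5.26 against 4.76 to 4.82) and the mean of the acinar genes (0.79, 10.77 against 5.74 to 6.80). It was lower in Kcnip1 (0.767, 5.37 against 6.46 to 6.79), Cldn7 (0.79, 7.70 against 8.10 to 8.20) and Insm1 (0.833, 6.96 against 8.38 to 8.67).

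The array labelled Pdx1-deficient replicate 1 was higher in Mki67 (0.754, 6.70 against 5.39 to 5.71), Cpb1 (0.86, 8.84 against 4.93 to 5.48) and the mean of the acinar genes (0.776, 6.45 against 5.69 to 5.86), and lower in Aldh1a3 (0.723, 5.97 against 6.23 to 6.33). Pdx1-deficient replicate 5 was higher in Rab3c (0.771, 8.15 against 6.06 to 6.54) and in the mean of the progenitor genes (0.735, 6.01 against 5.66 to 5.75). Pdx1-deficient replicate 2 was higher in the mean of the immediate early and dissociation stress genes (0.775, 9.15 against 8.85 to 8.92). Beta replicate 3 was lower in Ldha (0.72, 5.34 against 5.86 to 6.06) and higher in Hes1 (0.909, 6.69 against 6.26 to 6.30). Single values elsewhere were a high Peg10 in beta replicate 1 (0.715, 6.79 against 6.24 to 6.39), a low Usp18 in beta replicate 2 (0.76, 7.15 against 7.44 to 7.53), a low Slc31a1 in alpha replicate 3 (0.838, 6.17 against 7.26 to 7.47) and a high Irf1 in alpha replicate 4 (0.742, 9.09 against 6.69 to 7.31).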

How the results depend on the processing

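Leaving out the arrays labelled Pdx1-deficient replicate 1 and alpha replicate 2, or these and alpha replicate 5, was chosen only after the result was seen. For Pdx1-deficient against beta cells (217 genes) the count was 401 with dim clusters removed, which tests fewer genes, 29 quantile normalized again, 615 with array medians subtracted, 121 with trend and robust moderation, 89 in a fit of only these 2 groups, 8 with the replicate number as a block (6 higher and 2 lower, where all arrays without it gave 32 and 185), 626 without 2 arrays, 534 without 3, and 0 (Pdx1-deficient replicate 5) to 548 (replicate 1) without single arrays. The 217 genes, which were picked on these same arrays, kept their sign in every setting that tested them. For alpha against beta cells (806) it was 1316 with array weights, 1425 without 2 arrays, and 328 (alpha replicate 3) to 1430 (alpha replicate 2) without single arrays. For Pdx1-deficient against alpha cells (0 in limma) it was 1 each with dim clusters removed, trend and robust moderation and array weights, 177 without 2 arrays, 106 without 3, and 0 to 145 (alpha replicate 2) without single arrays. With enriched genes defined anew in each setting, alpha-enriched genes that rose (9) numbered 4 quantile normalized again, 14 without 3 arrays, 0 (median) with separate beta arrays, where the splits called a median of 3 alpha-enriched and 8 beta-enriched genes, and 0 (Pdx1-deficient replicate 5) to 15 (alpha replicate 2) without single arrays. Beta-enriched genes that fell (51) numbered 93 with dim clusters removed, 12 quantile normalized again, 121 with medians subtracted, 33 with 2 groups, 1 with the block, 155 without 2 arrays, 147 without 3, 0 with separate beta arrays, and 0 (Pdx1-deficient replicates 4 and 5) to 114 (replicate 1) without single arrays. The alpha-enriched share (0.325) was 0.182 without 2 arrays, 0.221 without 3, 0.196 on the linear scale, 0.183 with separate beta arrays, and 0.222 to 0.5035 without single arrays; the beta-enriched share (0.690) stayed between 0.555 and 0.795 without single arrays. Lists past camera in Pdx1-deficient against beta cells (3) were 5 quantile normalized again, 6 each with medians subtracted, array weights, 2 groups, without 2 arrays and without 3, 0 with an estimated correlation and 3 to 6 without single arrays. In alpha against beta cells (9) they were 2 with an estimated correlation and 7 to 11 without single arrays. In Pdx1-deficient against alpha cells (4) they were 9 with array weights, 7 without 2 arrays and without 3, 1 with an estimated correlation and by fry, and 3 to 7 without single arrays. Of 51 list medians 26 changed sign in at least 1 alternative, 3 of them where the list passed camera with all arrays or in that alternative: oxidative phosphorylation in Pdx1-deficient against alpha cells (0.1294 with array weights), and without 3 arrays acinar genes in alpha against beta cells (-0.114) and cell cycle genes in Pdx1-deficient against alpha cells (-0.173). Except where fewer genes or arrays are named, the cause was not tested. Of the remaining values of named genes 3046 stayed on their side of the threshold, 62 passed newly and 395 no longer passed; of list medians it was 1138, 68 and 12. Camera has no trend or robust setting, so lists have no value there. Residuals of arrays with the same replicate number correlated at -0.172 to 0.224, and at 0.00504 to 0.224 between beta and alpha arrays. In 7 of 30 comparisons with another group of 5, an array correlated best with its own number. These values do not show that the numbers pair the samples, and they cannot exclude it. Arrays give no read depth, and dim signals near background limit what can be seen.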

Other observations

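These values were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Islet hormone genes lay near the top of the scale in all 3 groups. Ins2 had 11.90 ± 0.08 (SD, n = 5) in beta, 12.00 ± 0.10 in alpha and 12.03 ± 0.08 in Pdx1-deficient arrays. Gcg had 12.35 ± 0.17, 12.74 ± 0.16 and 12.52 ± 0.19, and Sst 12.08, 12.14 and 11.61. Ppy had 12.34, 12.43 and 12.46, and Iapp 12.34, 12.00 and 12.18.

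Beta-cell genes with large differences that did not pass in Pdx1-deficient against beta cells were Slc2a2 (-1.83, limma adjusted p = 0.0915), Glp1r (-1.66, limma adjusted p = 0.0617), G6pc2 (-1.19, limma adjusted p = 0.0888) and Nkx6-1 (2.00-fold lower, limma adjusted p = 0.0676). Mafa had 6.52, 6.38 and 6.43 in beta, alpha and Pdx1-deficient arrays. The median SD of a gene was 0.172 in beta, 0.193 in alpha and 0.200 in Pdx1-deficient arrays.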
